A study of Mus musculus with 4 samples.

How the data were processed

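Single-nucleus RNA sequencing (10x Chromium 3' v3 chemistry) was carried out on liver of male C57BL/6 mice, per the labels. Nuclei came from punches of frozen liver, and tissue of 3 unrelated males was processed together for each library. The 4 libraries cross the exercise of the mother after birth (Run, mothers that ran, and Sed, sedentary mothers) with diet (medium fat and low fat). The design text gives diets of 21% and 13%, and the higher was taken as medium fat. The names of the deposited files carry HF for the libraries that the labels call medium fat, and the labels were followed. What the percentages are relative to, the age of the animals and the hour of collection were not given in the sources used here. Each group holds 1 library, so no test between groups was made and no p-value is given. A matrix of 3 pooled animals with no map from nuclei to animals is 1 sample.

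The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, not normalised, in matrices that hold all barcodes and not only those of nuclei. The counts came from Cell Ranger 4 per the file headers, while the submitters' processing notes name Cell Ranger 6.0.0, Seurat and the mouse build mm10 (GRCm38) without saying which step each served. Whether intronic reads were counted was not given in the sources used here. The matrices share 32285 features, of which 32158 matched the GENCODE vM21 annotation of GRCm38 by gene identifier, and coordinates come from that annotation.

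A barcode counted as a nucleus when its UMIs reached the larger of 500 and the 99th percentile of the 5000 deepest barcodes of its library divided by 10, with at least 300 genes and under 5% mitochondrial UMIs. The resulting UMI minimum was 2495.5 for Run medium fat, 1831.8 for Run low fat, 1597.3 for Sed medium fat and 1351.8 for Sed low fat, so shallow nuclei were admitted in unequal measure. Doublets were scored with a re-implementation of the Scrublet score that uses exact neighbours. The plan was to remove the calls of its own threshold, the valley of the simulated scores, but this threshold called 0, 0, 958 and 1 barcodes in the same order, and it had failed in 3 of the 4 libraries. The barcodes with the top 6% of scores were therefore removed in each library, a choice made after seeing the data.

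Nuclei of all 4 libraries were clustered together on log-normalised counts (2000 variable genes, 30 principal components, 15 neighbours, Leiden at resolution 1.0, no integration), which gave 31 clusters. Clusters were named from 15 lists of marker genes. A cluster's level for a list was the mean over its markers of the CPM (a gene's UMIs scaled to the total of the sum in the usual way) relative to the highest cluster. A cluster was called hepatocyte-like at a level of at least 0.4 with no other list at 0.15 or above. Another class needed a level of at least 0.45, at least 3 detected markers and no rival list above 0.5 of its own level. The hepatocyte list was not among these rivals and only had to lie below the class's own level. T or NK and B cell-like clusters thus kept their names at hepatocyte levels of 0.383 and 0.401, against 0.899 and 0.92 for their own lists. The cycling list did not count as a rival in either rule. Clusters with markers of several classes were called mixed, and the share of nuclei in them is given per library, since these levels were set after seeing the data. Shares are also given with each mixed cluster counted in the class that shares most of its 10 leading genes (at least 2), a count added after seeing the data. The plasma cell, erythroid, neutrophil, adipocyte and pancreatic acinar lists were set aside when naming clusters, because other cells here widely used their genes, which was also decided after seeing the data. Clusters led by mitochondrial transcripts stayed unnamed. Raw UMIs were then summed per class and library.

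Within the hepatocyte-like class, sums were scaled to CPM by the class's total UMIs, and genes with a mean of at least 10 CPM over the 4 libraries were kept, which left 8281. Differences are log2 ratios of CPM with 0.5 counts added. Each CPM has an exact Poisson 95% interval, each ratio an exact conditional binomial one, and each share an exact (Clopper-Pearson) one. The difference of differences, Sed over Run on medium fat minus Sed over Run on low fat, has a normal approximation of its counting error. All of these intervals cover counting error only, not the spread between animals. The number of genes at least 2-fold apart is given as a description of these libraries.

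Gene lists were fixed before the data were examined, together with the contrasts, the marker genes, the rule for named genes and most of the alternative settings. The 29 lists were fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, fatty acid oxidation and PPAR alpha targets, lipid droplet, gluconeogenesis and glucose output, glycolysis with glycogen and glucose uptake, insulin and growth factor signalling, bile acid synthesis and transport, lipoproteins and sterol transport, pericentral and periportal hepatocyte genes, circadian clock, male-biased and female-biased liver genes, acute phase and IL-6 response, interferon response, endoplasmic reticulum stress, immediate early and heat shock response, oxidative stress and xenobiotic response, one-carbon and sulphur amino acids, amino acid and urea metabolism, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, ribosomal proteins, nuclear retained RNA, secreted hepatocyte transcripts, fibrosis and stellate activation, macrophage lipid and inflammation, and sinusoidal endothelial function. A list with at least 4 measured members was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, each gene drawn from within 100 ranks of mean expression. A list is said to stand apart below percentile 2.5 or above 97.5, as a description of these libraries and not a test.

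The genes named per contrast in hepatocyte-like nuclei were the 8 with the highest and the 8 with the lowest log2 ratio, among genes with a mean of at least 50 CPM over the 4 libraries and at least 200 UMIs over the pair compared. Mitochondrial and predicted genes were left out, as were genes over 3 times more abundant in barcodes with 10 to 100 UMIs than in hepatocyte-like nuclei in either library of the pair. To these came the 4 members of each list that stood apart with the largest ratio in its direction, the 8 genes with the largest absolute difference of differences, and the 8 genes with the largest ratios of the same sign in both arms of each contrast. In other classes with at least 100 nuclei in every library, genes with a mean of at least 50 CPM and at least 100 UMIs over the 4 libraries were compared, and the 3 highest and 3 lowest per contrast were eligible. Barcodes with 10 to 100 UMIs numbered 5187 in Run medium fat, 4476 in Run low fat, 8792 in Sed medium fat and 4365 in Sed low fat, against 92935, 93358, 94397 and 101581 with over 100 UMIs. They held between 0.19% and 0.39% of the UMIs and carried lung transcripts (between 0.962% and 3.31% of their UMIs from Sftpc), so their profile need not be that of most empty droplets. The rule took 187 genes in hepatocyte-like nuclei, and the text gives those that describe each contrast best. Genes named outside it are said to be so, and some genes that the rule took are not reported here.

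The engine of these ratios and lists was tested on counts simulated for Sed against Run on medium fat over 8281 genes, with 50 genes raised or lowered at each fold size. Of these, 0 of 50 at 1.5-fold, 30 of 50 at 2-fold, 50 of 50 at 3-fold and 50 of 50 at 4-fold came out at least 2-fold apart, and all had the right direction. The interval held the known ratio for 46, 48, 48 and 49 of 50 genes in the same order and for 94.9% of 8081 unchanged genes. One list raised 1.5-fold came out at a median of 0.57 and stood apart, as did 0 of 24 other lists that share no gene with it. The simulated libraries shared a common profile, apart from the raised list, with independent counting error. The result therefore does not show how often lists whose genes move together stand apart between single pools.

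The alternative settings written beforehand were fixed minimums of 500, 1000 and 2000 UMIs, mitochondrial limits of 1% and 10%, no doublet removal, resolutions 0.5 and 2.0, TMM factors (edgeR) and DESeq2 size factors in place of total UMIs, gene minimums of 2 and 50 CPM, nuclei thinned to 1000 UMIs, the mean of per-nucleus CPM, all nuclei summed without classes, and subtraction of the profile of barcodes with 10 to 100 UMIs as free RNA. Resolutions 0.5 and 2.0 and the 10% limit were planned for the shares of classes and added for expression after seeing the data. The other alternatives chosen after seeing the data were the doublet score's own threshold, a free RNA profile from barcodes with 100 to 500 UMIs, thinning under a common minimum of 2000 UMIs, and TMM factors with genes of 2 to 50 CPM. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, scikit-image 0.26.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. Kupffer, T or NK, B, cholangiocyte, mesothelial and plasmacytoid dendritic cell-like classes and cycling nuclei held under 100 nuclei in at least 1 library, and expression was not compared within them.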

Results

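Nuclei were sequenced from the livers of male mice whose mothers had run (Run) or stayed sedentary (Sed) after birth, on a medium fat or a low fat diet. The series title asks whether a sedentary mother worsens the metabolic effect of a moderately fat-rich diet in males, and the design crosses both factors. The 4 libraries, 1 per group, were each made from 3 pooled males, so there are no replicates and no difference below could be set against the spread between animals. The matrices held 73774011 UMIs for Run medium fat, 62610888 for Run low fat, 78864115 for Sed medium fat and 53421873 for Sed low fat. After filtering, 5581, 5911, 10728 and 7734 nuclei remained in the same order, with medians of 4121, 3181, 2700 and 2185.5 UMIs and 2069, 1751, 1569 and 1328.5 genes. Intervals are 95% throughout and cover counting error only.

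The libraries matched their male label. Xist, the RNA of the inactive X chromosome, stood between 0.407 CPM in Run medium fat and 0.907 CPM in Sed low fat, while 4 genes of the Y chromosome summed to 524.5, 497, 467.5 and 486.6 CPM in Run medium fat, Run low fat, Sed medium fat and Sed low fat. Mitochondrial transcripts took 0.0971%, 0.036%, 0.0672% and 0.064% of the UMIs of nuclei in that order.

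Hepatocyte-like nuclei, named from genes such as Alb and Apob, made up 52.2% (50.9 to 53.5) of nuclei in Run medium fat, 68.2% (67 to 69.4) in Run low fat, 29.95% (29.1 to 30.8) in Sed medium fat and 47.2% (46.1 to 48.3) in Sed low fat. Sinusoidal or vascular endothelial cell-like nuclei, with markers such as Stab2 and Ptprb, made up 12.1% (11.3 to 13), 7.93% (7.26 to 8.65), 40.9% (39.9 to 41.8) and 19.25% (18.4 to 20.15) in the same order. Stellate cell-like nuclei, the vitamin A-storing cells marked by Reln and Lrat, took 3.49%, 1.76%, 7.61% and 3.52%, and Kupffer cell or macrophage-like nuclei, marked by Clec4f and Vsig4, 2.11%, 1.05%, 9.415% and 2.88%. T or NK cell-like nuclei (1.63%, 1.455%, 1.42% and 2.16%) and B cell-like nuclei (1.34%, 1.78%, 1.16% and 1.14%) were few in every library. Mixed clusters, which carried markers of several classes, held 23.5%, 16.6%, 5.68% and 21.85% of nuclei. With the mixed clusters led by the same genes counted in, the Kupffer share was 11.6% (10.8 to 12.5), 4.585% (4.07 to 5.15), 12.2% (11.6 to 12.8) and 10.6% (9.91 to 11.3), and the endothelial share 22.65%, 17.19%, 42.24% and 28.6%. The UMI minimum and the depth differed between libraries and can set these shares: at common minimums of 1000 and 2000 UMIs the endothelial-like share in Sed medium fat was 1.244 and 1.829 times that in Run medium fat, against 3.368 times here, and 1.623 and 4.453 times that in Sed low fat, against 2.122 times here. At a minimum of 500 UMIs the hepatocyte-like share was 26.56%, 52.06%, 16.27% and 34.57% in the order above, and the endothelial-like share was 34.87%, 27.57%, 33.34% and 37.09%, so that Sed medium fat no longer had the highest.

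**Figure D1:**
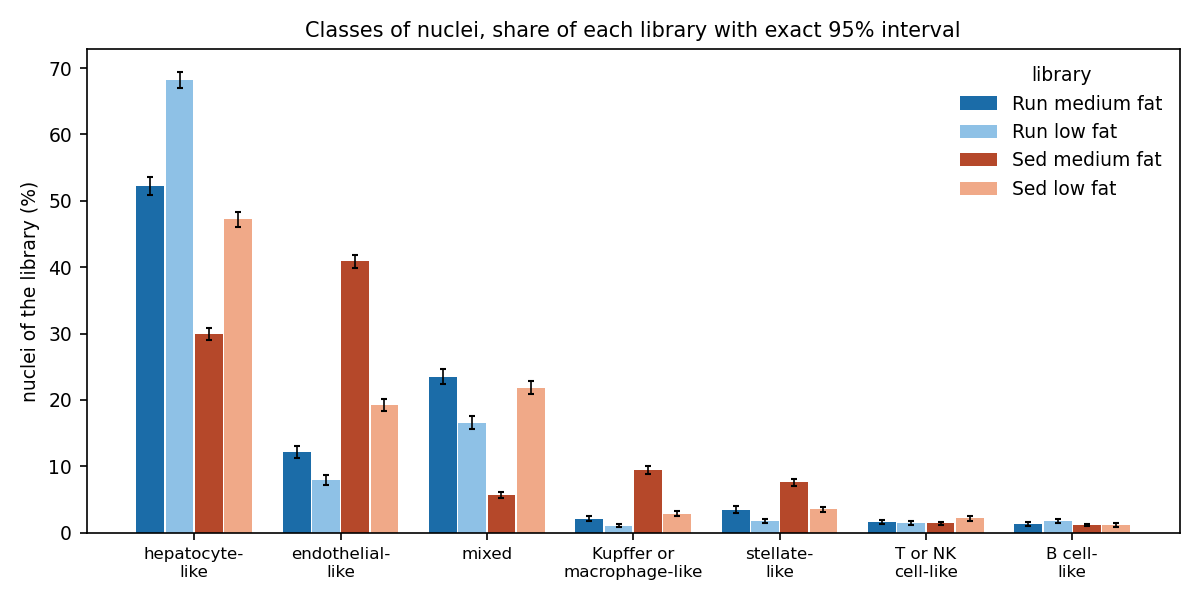
Percent of nuclei (vertical axis) per class in each of the 4 libraries, with bars for the share and lines for the exact 95% binomial interval, which covers counting error only. Endothelial-like nuclei reach 40.9% in Sed medium fat and 7.93% in Run low fat.

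Expression was compared in hepatocyte-like nuclei, of which there were 2914 in Run medium fat, 4030 in Run low fat, 3213 in Sed medium fat and 3652 in Sed low fat. The libraries fell largely into different clusters within this class. Cluster 2 held 70.05% of the hepatocyte-like nuclei of Run low fat, cluster 4 held 67.01% of those of Sed medium fat, and cluster 3 held 47.74% of those of Run medium fat and 45.13% of those of Sed low fat. Each ratio below therefore compares libraries whose hepatocyte-like nuclei lie mostly in different clusters.

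On medium fat, hepatocyte-like nuclei of Sed had more RNA of genes of fatty acid synthesis and oxidation than those of Run, and less of acute phase, periportal and amino acid genes. Pklr, the liver pyruvate kinase, stood at 405 CPM in Sed and 84.6 CPM in Run (log2 2.26, 2.17 to 2.35). Gys2, the liver glycogen synthase, was 4.72-fold higher (log2 2.24, 2.17 to 2.31), and Fabp1, which binds fatty acids in the hepatocyte, was 4.01-fold higher (log2 2.00, 1.91 to 2.09). Among genes lower in Sed, Abcb11, the bile salt export pump, had a log2 ratio of −1.58 (−1.64 to −1.53), Cyp2c70, which makes the muricholic acids of mice, −1.63, and Aass, the first enzyme of lysine breakdown, −1.56. The other genes with the highest ratios were Rad51b, a DNA recombination gene (2.61), Klf10, a transcription factor (2.37), Arrdc3, an arrestin-domain protein (2.34), Hsd17b6, a hydroxysteroid dehydrogenase (2.21), and Inmt, an amine methyltransferase (1.91). The others with the lowest were Pdgfrl (−3.15), the sulphotransferase Sult1d1 (−1.74), Hip1r (−1.65), the ferritin receptor Scara5 (−1.64) and the cystine transporter subunit Slc3a1 (−1.51).

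Fatty acid and triglyceride synthesis genes stood apart from random lists in this contrast, with a median log2 ratio of 0.40 and 15 of 21 members higher in Sed. They included Acly, which makes cytosolic acetyl-CoA (1.65), Srebf1, the transcription factor of lipogenesis (1.06), and Fasn, fatty acid synthase (1.05). The list of fatty acid oxidation and PPAR alpha targets was higher as well, at a median of 0.28 (19 of 25 members), with the peroxisomal thiolase Acaa1b at 1.22 and Cpt1a, the gate of mitochondrial fatty acid entry, at 0.71. Of its members 2 were at least 2-fold higher and 2 at least 2-fold lower, Cyp4a10 lying at −1.04. The lipid droplet list had a median of 0.34, with the droplet coat protein Plin2 at 1.18 and the lipase inhibitor G0s2 at 0.95, but −0.07 with TMM factors and genes of 2 to 50 CPM. Interferon response genes had a median of 0.40, 8 of 9 members being higher, with Trim30a at 1.06. Acute phase genes were lower (−0.44, 15 of 16 members), among them Saa4 (−1.36) and the fibrinogen chain Fga (−1.02). Periportal genes (−0.30, 14 of 17) included the glycine decarboxylase Gldc (−1.31) and the urea cycle genes Ass1 (−0.79) and Cps1 (−0.71), which the amino acid and urea list (−0.22) shares. The one-carbon and sulphur amino acid list lay at −0.20, with Csad of taurine synthesis at −1.44 and cystathionine beta-synthase, Cbs, at −1.13. Mitochondrially encoded transcripts had a median of −0.33, mt-Co1 lying at −0.39. Ribosomal protein genes had a median of −0.01 where random lists of like expression had 0.15, and 0.07 with nuclei thinned to 1000 UMIs. Sinusoidal endothelial genes, markers of another cell type, were at 0.59 in these hepatocyte-like nuclei, 7 of 7 being higher in Sed. The bile acid list, which holds Abcb11, had a median of 0.11 (13 of 20 members higher in Sed), or −0.04 (10 of 20) with TMM factors. The glycolysis and glycogen list had one of 0.20 (12 of 17), or 0.05 with TMM factors. Both medians were within the range of random lists. So were 0.01 for insulin and growth factor signalling, 0.07 for cholesterol synthesis, 0.02 for gluconeogenesis, 0.14 for lipoproteins, 0.18 for pericentral and −0.02 for male-biased genes. The same held for 0.08 for endoplasmic reticulum stress, 0.02 for immediate early, −0.13 for oxidative stress and xenobiotic, −0.02 for secreted, 0.07 for nuclear-encoded oxidative phosphorylation, −0.19 for nuclear retained and 0.24 for macrophage genes. The female-biased and the fibrosis list each had 2 measured members, too few to describe. Lists that stood apart numbered 12 in this contrast, but 6 with free RNA of barcodes with 10 to 100 UMIs subtracted. In all, 182 genes lay at least 2-fold apart with the higher level in Sed and 94 with the lower, of 8281 (65.9% higher). With TMM factors, which moved the median of all genes by −0.15, these were 109 and 135 (44.7% higher). The list medians moved by the same shift, to 0.25 for fatty acid synthesis (15 of 21 members higher), 0.13 for fatty acid oxidation (15 of 25), 0.19 for lipid droplet, 0.25 for interferon (7 of 9), −0.45 for periportal, −0.35 for one-carbon, −0.37 for amino acid and −0.16 for ribosomal protein genes. With all nuclei summed without classes, fatty acid synthesis turned to −0.07, fatty acid oxidation to −0.13 and ribosomal protein genes to 1.46.

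On low fat the Sed library had more RNA than the Run library of genes of methionine, glucose output and acute phase metabolism, and less of cholesterol synthesis genes. Bhmt, which remethylates homocysteine from betaine, stood at 4292 CPM in Sed and 314 CPM in Run (log2 3.77, 3.73 to 3.82). Fkbp5, a glucocorticoid-induced chaperone, was 6.49-fold higher (log2 2.70, 2.65 to 2.75), and Insig2, which holds the sterol sensor in the endoplasmic reticulum, 6.73-fold higher (log2 2.75, 2.65 to 2.85). G6pc, the last enzyme of glucose output, had a log2 ratio of 2.00 (1.94 to 2.05). Lower in Sed were Fads2, a fatty acid desaturase (−1.97), Fabp1 (−1.88) and Gys2 (−1.67), all of which had been higher in Sed on medium fat. Further genes at the top were Moxd1 (3.80, from 2.77 CPM in Run), the fatty acid hydroxylase Cyp4a10 (2.96), the glycogen-targeting subunit Ppp1r3c (2.69), Saa4 (2.47) and Scara5 (2.45). Those at the bottom included Hsd17b6 (−2.49), Inmt (−2.03), Arrdc3 (−1.91), the epoxygenase Cyp2c23 (−1.76) and the steroid enzyme Hsd3b5 (−1.67).

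The one-carbon list had a median of 0.64 (15 of 18 members higher in Sed), with cysteine dioxygenase, Cdo1, at 1.83 and Nnmt, which methylates nicotinamide, at 1.65. Endoplasmic reticulum stress genes lay at 0.75 (11 of 14), among them the chaperones Hspa5 (0.81) and Hyou1 (1.39). Acute phase genes (0.43, 13 of 16) included Saa1 (2.78) and the interleukin receptor Il1r1 (1.94). Periportal genes had a median of 0.43, Gldc lying at 1.44, and amino acid genes one of 0.38, with Hpd of tyrosine breakdown at 1.26. Gluconeogenesis genes (0.29, 11 of 16 members higher) held the mitochondrial carrier Slc25a25 (1.35) and Tat, tyrosine aminotransferase (0.92), beside G6pc. Bile acid genes went both ways, 11 members being higher in Sed and 9 lower (median 0.17, or −0.05 with all nuclei summed without classes), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.32 and Cyp27a1 at 1.64. Lipoprotein genes stood at 0.24 (−0.09 with free RNA of barcodes with 10 to 100 UMIs subtracted), with Apoa1 of high-density lipoprotein at 1.42, and secreted hepatocyte transcripts, which also hold Apoa1, at 0.13. Pericentral genes were at 0.17, with glutamine synthetase, Glul, at 0.60. The immediate early and heat shock list had a median of 0.53, with the stress gene Gadd45g at 2.68, but −0.17 with TMM factors and genes of 2 to 50 CPM. The oxidative stress and xenobiotic list, at 0.25 with 8 of 14 members higher, and −0.59 under that same setting, held Cyp2b10, a target of the receptor CAR, at 3.76 and Cyp3a11 at 1.15. Ribosomal protein genes (0.44), mitochondrially encoded transcripts (0.33) and sinusoidal endothelial genes (0.56) were higher in Sed. Cholesterol synthesis genes (−0.60, 19 of 22 members) and interferon genes (−0.41, 7 of 9) were lower, with the sterol carrier Stard4 at −1.29 and squalene synthase, Fdft1, at −0.88. With all nuclei summed without classes, the pericentral median turned to −0.10, that of secreted transcripts to −0.04 and that of interferon genes to 0.18. At least 2-fold apart were 213 genes higher in Sed and 176 lower.

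Between the diets in Sed, the medium fat library had more RNA of fatty acid oxidation genes and less of drug metabolism, chaperone and acute phase genes. Fabp1 stood at 329 CPM on medium and 79.8 CPM on low fat (log2 2.04, 1.94 to 2.15). Cyp3a11, a drug-metabolising cytochrome, had a log2 ratio of −2.62 (−2.68 to −2.56), and Cyp2b10, seen in 176 CPM on low fat and 0.612 CPM on medium fat, one of −8.09 (−9.23 to −7.28). Grip1, a scaffold protein (2.43), Gys2 (2.36), Pklr (2.23), Hsd17b6 (2.19), St8sia3os (2.05), Klf10 (1.85) and the cadherin Cdh18 (1.82) were also among the highest. Insig2 (−2.45), Cyp2c70 (−2.16), Ppp1r3c (−2.08), Sult1d1 (−2.06), Abcb11 (−1.85), Cyp2c29 (−1.76) and Saa4 (−1.69) were among the lowest. The fatty acid oxidation list had a median of 0.47 (22 of 25 members), with Decr1 at 1.21, though 2 members were at least 2-fold lower against 3 at least 2-fold higher. The interferon list had a median of 0.63 (9 of 9), with Herc6 at 1.09 and Parp14 at 0.94. Pericentral genes had a median of 0.27, with the stem cell marker Lgr5 at 0.95 and the glutamate transporter Slc1a2 at 0.63. At clustering resolution 2.0 this median was −1.07, and the ratios of Lgr5 and Slc1a2 reversed. It was 0.15 with TMM factors and −0.04 with all nuclei summed. Cluster 14, with Lgr5 and Slc1a2 among its leading genes, was called mixed and is not counted here. It held 37 nuclei of Sed medium fat and 215 of Sed low fat. Lower lists were endoplasmic reticulum stress (−0.67, 13 of 14; Creld2 −1.36), xenobiotic response (−0.52, 13 of 14; Gstm1 −1.52), acute phase (−0.48), immediate early (−0.41), secreted transcripts (−0.34, Serpina3k −1.08), periportal (−0.33, the histidine ammonia-lyase Hal −0.89), one-carbon (−0.32, Bhmt −1.67), cholesterol synthesis (−0.25) and ribosomal protein genes (−0.24, or 1.34 with all nuclei summed). At least 2-fold apart were 255 genes higher on medium fat and 110 lower (69.9% higher), or 178 and 157 with TMM factors (53.1% higher), which moved the median of all genes by −0.12.

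Between the diets in Run, the medium fat library had more RNA of methionine cycle, glucose output and acute phase genes and less of lipid and cholesterol synthesis genes. Bhmt stood at 3054 CPM on medium and 314 CPM on low fat (log2 3.28, 3.24 to 3.33), and G6pc was 4.78-fold higher (log2 2.26, 2.20 to 2.31). Srebf1 had a log2 ratio of −1.67 (−1.78 to −1.57), Fasn −1.49 and Scd1, the desaturase that makes oleate, −1.38. Moxd1 (5.99), Pdgfrl (4.11), Cyp4a10 (2.93), Scara5 (2.63), Nnmt (2.42) and the hepatokine Fgl1 (2.34) were among the highest. Arrdc3 (−3.38), Inmt (−3.22), Hsd17b6 (−2.50), Clec2h (−2.46), Osgin1 (−2.04), Cyp2a5 (−2.01), Hsd3b5 (−1.91) and Fabp1 (−1.84) were the lowest. Fatty acid synthesis genes had a median of −0.73 (16 of 21 members lower) and cholesterol synthesis genes one of −0.87 (19 of 22), with the sterol desaturase Sc5d at −1.42. The glycolysis and glycogen list lay at −0.28 (10 of 17 members lower), Ugp2 at −1.24, and the xenobiotic list at −0.34, the carboxylesterase Ces2a at −1.58. Higher on medium fat were one-carbon (0.56, 11 of 18 members; Mat1a, which makes S-adenosylmethionine, 1.39), acute phase (0.53, 16 of 16 members), mitochondrially encoded (0.51), gluconeogenesis (0.36, Got1 1.15), periportal (0.35, angiotensinogen, Agt, 1.48), ribosomal protein (0.19) and fatty acid oxidation genes (0.18, Slc25a20 0.97). The immediate early list lay at 0.23 with 4 members higher and 4 lower, or −0.11 with genes from 2 CPM and −0.07 with TMM factors and genes of 2 to 50 CPM. Male-biased genes had a median of 0.17 (9 of 17 members higher), with the elongase Elovl3 at 4.55 and the urinary protein gene Mup20 at 0.89, but −0.16 with genes from 50 CPM and −0.04 with free RNA of barcodes with 100 to 500 UMIs subtracted or with all nuclei summed. At least 2-fold apart were 218 genes higher on medium fat and 166 lower.

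The ratios of Sed over Run ran in opposite directions in the 2 diets for many of the genes just named. Across 8281 genes, which are not independent replicates, the ratios on medium fat and on low fat had a Pearson correlation of −0.53 (−0.56 to −0.50 when genes were redrawn) and a Spearman correlation of −0.41. For the ratios between the diets in Sed and in Run these were −0.33 and −0.28. Of 131 genes at least 2-fold apart between Sed and Run in both diets, 128 had opposite directions and 3 the same. With all nuclei summed without classes, which counts the other cell types in, the correlation was 0.25 for Sed over Run and 0.16 for the diets, and 12 of 67 list medians that stood apart turned sign. With free RNA of barcodes with 10 to 100 UMIs subtracted these correlations were −0.33 and −0.14, and with TMM factors and genes of 2 to 50 CPM the one for the diets was −0.21. The numbers of genes at least 2-fold apart moved by over 1.5 times in every contrast with genes from 2 or from 50 CPM, and in nearly all with free RNA of barcodes with 10 to 100 UMIs subtracted. For Sed over Run on medium fat they came to 526 and 147, 65 and 53, and 440 and 401 under these settings, and to 802 and 195 with all nuclei summed. Mother, diet and mother by diet took 17.5%, 27.2% and 55.3% of the sum of squares over genes.

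The largest differences of differences (Sed over Run on medium fat minus that on low fat) belonged to Bhmt at −4.96, −5.00 to −4.91 (ENSMUSG00000074768, GRCm38 chromosome 13, 93616675 to 93637961), Hsd17b6 at 4.70, 4.45 to 4.94 (ENSMUSG00000025396, chromosome 10, 127990936 to 128007611), Moxd1 at −4.29, −4.73 to −3.84 (ENSMUSG00000020000, chromosome 10, 24223517 to 24302790) and Insig2 at −4.26, −4.40 to −4.12 (ENSMUSG00000003721, chromosome 1, 121304353 to 121332589). Next came Arrdc3 at 4.25, 4.09 to 4.41 (ENSMUSG00000074794, chromosome 13, 80883384 to 80896042), Scara5 at −4.09, −4.20 to −3.99 (ENSMUSG00000022032, chromosome 14, 65666403 to 65764826), Pdgfrl at −4.00, −4.31 to −3.70 (ENSMUSG00000031595, chromosome 8, 40926212 to 40990785) and Cyp4a10 at −4.00, −4.26 to −3.74 (ENSMUSG00000066072, chromosome 4, 115518264 to 115533649). By list, the median difference of differences was −0.99 for one-carbon, −0.94 for periportal, −0.89 for acute phase, −0.65 for mitochondrially encoded, −0.61 for endoplasmic reticulum stress, −0.50 (1.10 with all nuclei summed) for ribosomal protein, −0.48 for gluconeogenesis and −0.39 for amino acid genes. It was 1.02 for interferon, 0.68 for fatty acid synthesis, 0.65 for cholesterol synthesis and 0.45 (0.29 with TMM factors) for glycolysis and glycogen genes, and −0.53 for immediate early genes, or 0.62 with TMM factors and genes of 2 to 50 CPM. In all 697 genes had a difference of at least 2-fold upward and 377 downward (64.9% upward), or 518 and 515 with TMM factors (50.15%), which moved the median by −0.16.

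Some genes had the same direction in both diets. G0s2 was higher in Sed, at 0.95 on medium and 1.33 on low fat, as was Sik1, a salt-inducible kinase (0.58 and 0.99). Onecut1, a hepatocyte transcription factor, was lower (−0.93 and −1.54), and so was Ablim1 (−0.93 and −0.71). On medium against low fat, Grip1 (2.43 in Sed and 1.89 in Run), the muscarinic receptor Chrm3 (1.29 and 2.17) and Pde7b (0.84 and 0.87) were higher in both, and Angptl8, an insulin-induced inhibitor of lipoprotein lipase, was lower (−1.27 and −1.65).

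**Figure D2:**
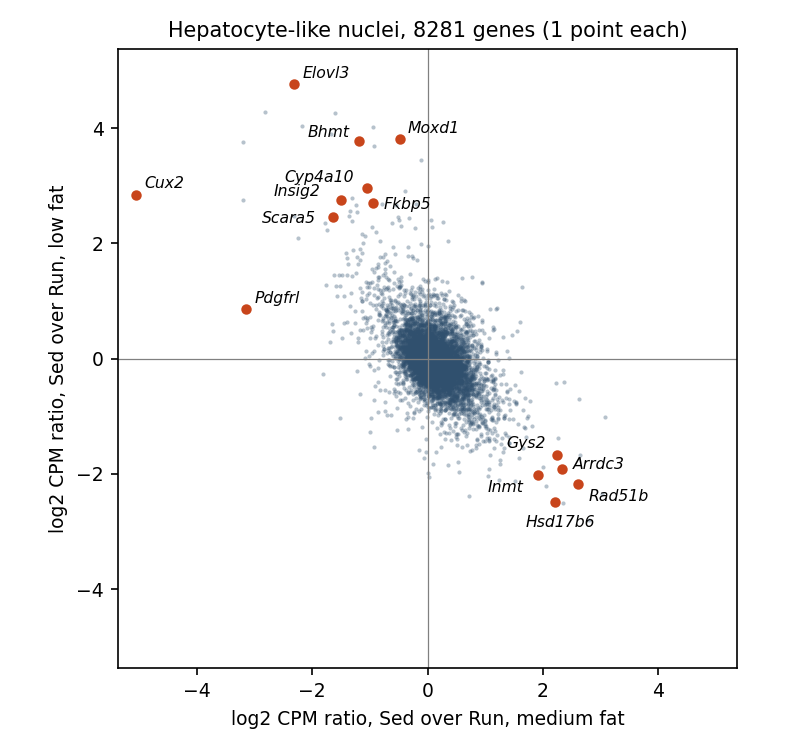
Log2 ratio of Sed over Run in hepatocyte-like nuclei for 8281 genes, on medium fat (horizontal axis) and low fat (vertical axis), with 1 point per gene and some genes labelled. Cux2, labelled here, was chosen after its values were seen, and the points run from upper left to lower right (Pearson −0.53).

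**Figure D3:**
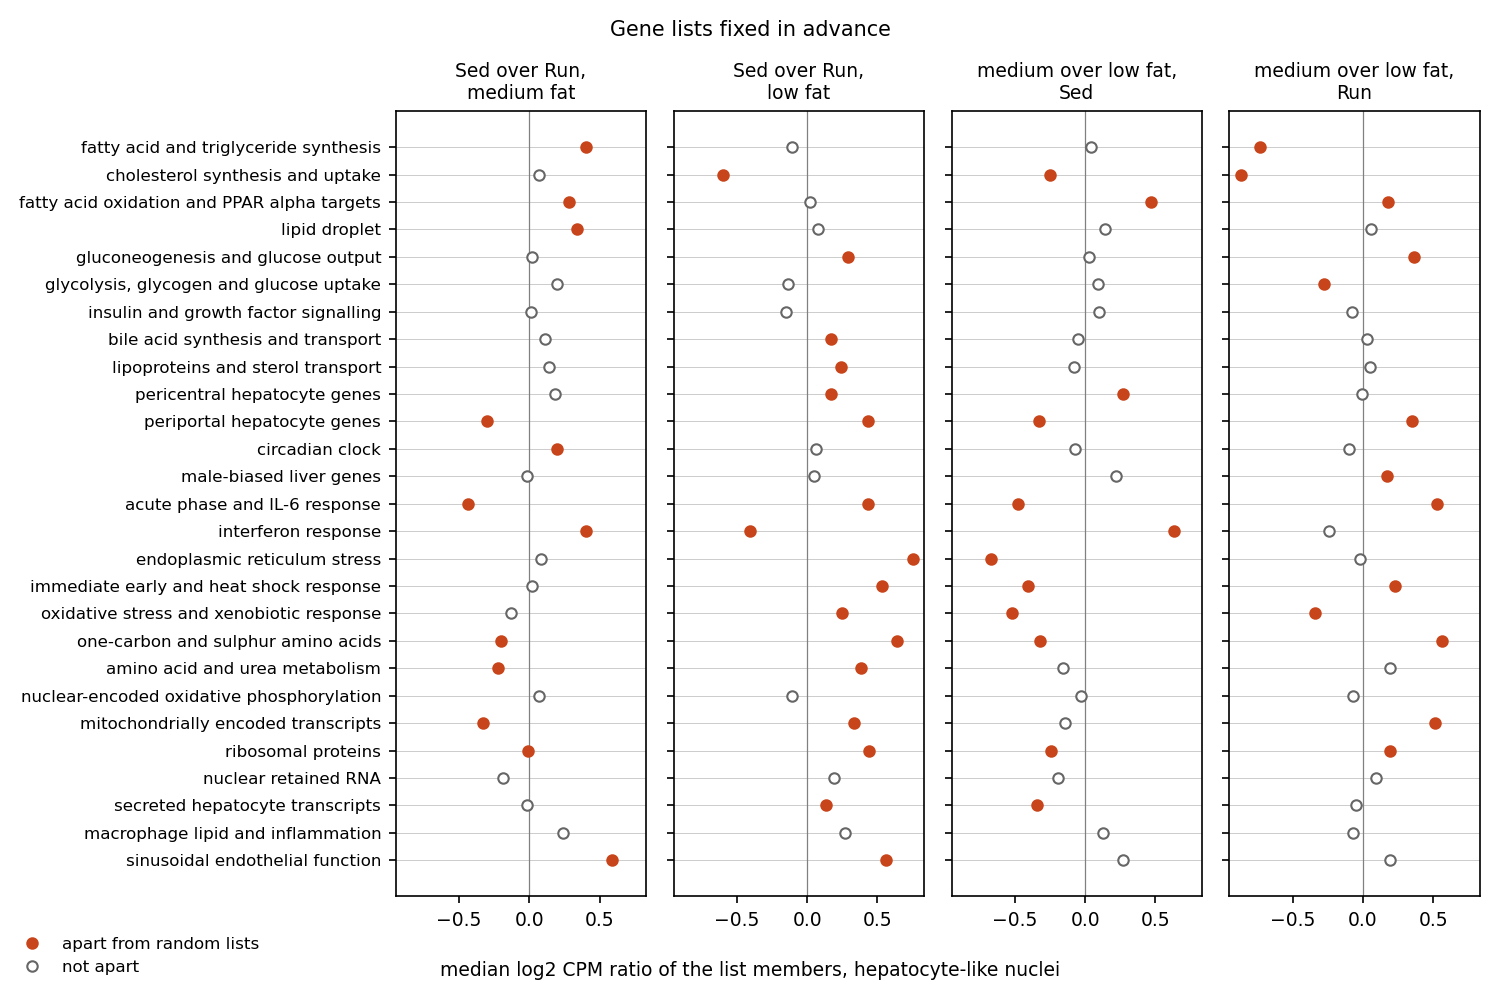
Median log2 ratio (horizontal axis) of 27 gene lists in each of the 4 contrasts, with filled points for lists that stand apart from random lists of like expression. The acute phase list lies at −0.44 for Sed over Run on medium fat and 0.43 on low fat.

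Some core clock genes, chosen after their values were seen, paired Run medium fat with Sed low fat and Run low fat with Sed medium fat. Arntl, the clock activator, stood in hepatocyte-like nuclei at 58.4 CPM in Run medium fat and 71.7 in Sed low fat, against 10.6 in Run low fat and 6.31 in Sed medium fat. Nr1d1, a repressor of Arntl, had the opposite order, at 5.46 and 9.08 CPM against 46.4 and 44.6, and so did Dbp, at 10.9 and 23.1 against 73.2 and 68.2. Others did not pair, such as Bhlhe40, at 170.4, 169.8, 292 and 232 CPM in Run medium fat, Run low fat, Sed medium fat and Sed low fat, Hlf, at 209, 202, 250.2 and 203, and Per1, at 58.0, 69.7, 69.1 and 68.2. The clock list had a median of 0.20 for Sed over Run on medium fat (0.05 with TMM factors and −0.29 with all nuclei summed), with 10 members higher and 8 lower. In endothelial-like nuclei Nr1d1 stood at 18.2, 45.1, 49.98 and 18.7 CPM in Run medium fat, Run low fat, Sed medium fat and Sed low fat, and Per2, a clock repressor, at 107, 62.3, 69.5 and 178, while Arntl lay between 9.25 and 11.5 CPM in all 4. These Arntl values rested on 25, 12, 104 and 32 UMIs. Cry1 stood in endothelial-like nuclei at 47.95, 24.4, 20.3 and 57.3 CPM. In stellate-like nuclei Per2 stood at 149, 59.5, 66.3 and 197 CPM in that order. Nr1d1 stood there at 18.3, 37.2, 49.5 and 12.9 CPM, Dbp at 27.4, 52.0, 58.6 and 25.8, and Cry1 at 36.5, 18.6, 14.65 and 66.35, with only 5 Cry1 UMIs in Run low fat. Tef did not pair in stellate-like nuclei, at 258.6, 286.1, 222.7 and 309.7 CPM.

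**Figure D4:**
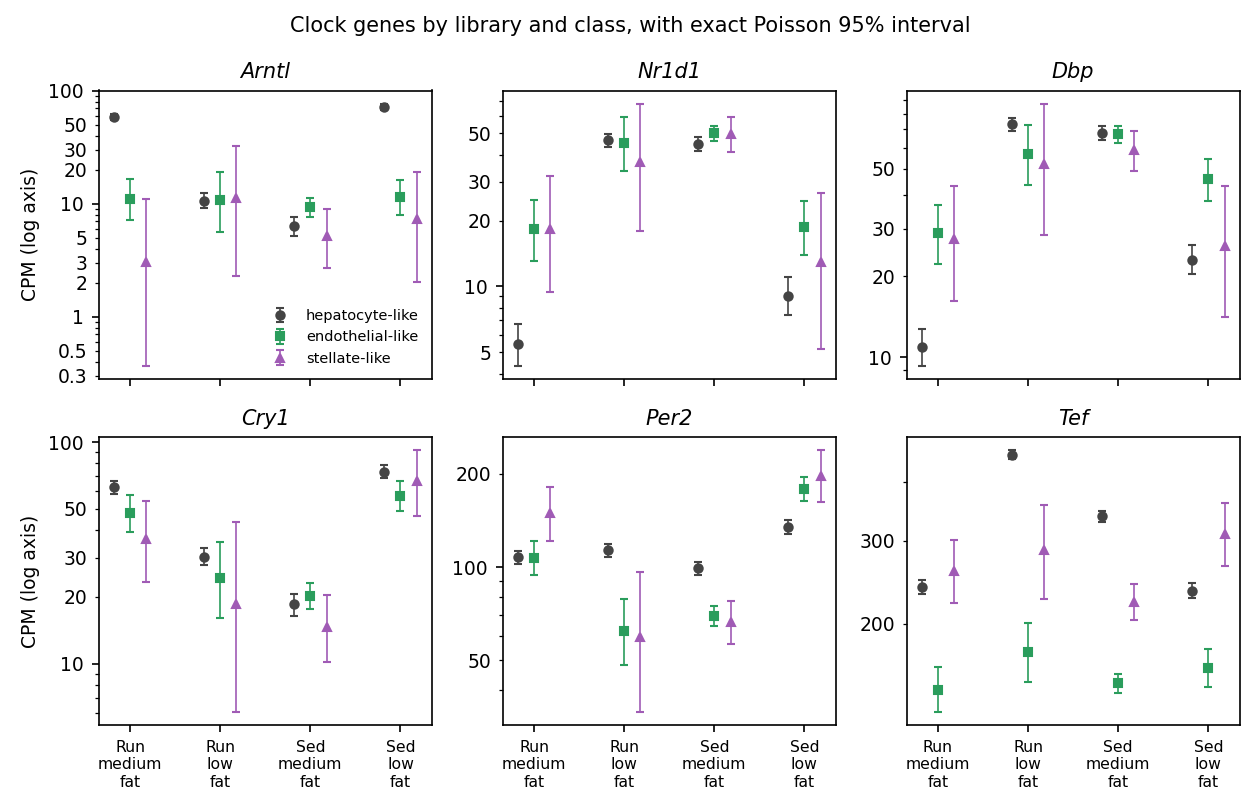
CPM (log axis) of Arntl, Nr1d1, Dbp, Cry1, Per2 and Tef by library in hepatocyte-, endothelial- and stellate-like nuclei, with exact 95% Poisson intervals. Arntl in hepatocyte-like nuclei lies at 58.4 CPM in Run medium fat and 6.31 CPM in Sed medium fat.

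In endothelial-like nuclei Zbtb16, a zinc finger transcription factor, stood at 1088 CPM in Run medium fat, 121 in Run low fat, 265 in Sed medium fat and 1408 in Sed low fat (log2 of Sed over Run −2.04, −2.12 to −1.96 on medium and 3.54, 3.29 to 3.80 on low fat). It was higher in hepatocyte-like nuclei in every library, at 1951, 814, 1164 and 2271 CPM in that order. The integrin Itga8 (1.11) and the sialyltransferase St6galnac3 (1.05) were higher in Sed on medium fat, and both were lower in Sed on low fat. Itga8 stood at 44.4, 88.5, 95.95 and 34.9 CPM and St6galnac3 at 535, 1171, 1111 and 537 CPM in the same order of libraries. The growth factor Nrg1 was higher on medium than on low fat in Sed (1.45). On low fat, Per2 (1.51) and Qsox1 (1.83) were higher in Sed and Slc45a4 lower (−1.82), Qsox1 standing at 37.9 CPM in Run against 83.3 in hepatocyte-like nuclei. Interferon genes had a median of 0.32 for Sed over Run on medium fat, and sinusoidal endothelial genes one of 0.07. Hepatocyte markers took 0.46%, 0.528%, 0.32% and 0.535% of the UMIs of these nuclei, and Gldc, Bhmt and G6pc, which also led here, stood far higher in hepatocyte-like nuclei (Bhmt 3054 against 308 CPM in Run medium fat). Of 3825 genes, 4 were at least 2-fold higher and 32 lower in Sed on medium fat, and 32 and 42 on low fat, with a Pearson correlation of −0.12 between the diets. Without doublet removal, 22 lay at least 2-fold apart on medium fat, and 23 with the doublet score's own threshold.

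In stellate-like nuclei Aldh1a1, which makes retinoic acid, stood at 1943, 621, 935 and 2827 CPM in Run medium fat, Run low fat, Sed medium fat and Sed low fat (log2 of Sed over Run on low fat 2.18, 1.96 to 2.43). Thsd7a was 7.23-fold higher in Sed on low fat (log2 2.85, 2.12 to 3.80), and the calcium channel gene Cacna1c lower (−1.67). On medium fat the interferon-induced GTPase Iigp1 was higher in Sed (1.60) and Neto1 lower (−1.52), and Oasl2, also induced by interferon, was higher on medium than on low fat in Sed (1.28). The interferon list had a median of 0.54 for Sed over Run on medium fat, and the fibrosis list, with 10 members measured here, one of −0.01. Hepatocyte markers took 0.327%, 0.428%, 0.266% and 0.428% of the UMIs of these nuclei in the order above. Gldc, Aass and Bhmt, which also led here, stood far higher in hepatocyte-like nuclei (Bhmt 3054 against 182.6 CPM in Run medium fat). Of 3590 genes, 19 were at least 2-fold higher and 11 lower in Sed on medium fat, and 86 and 84 on low fat, with a Pearson correlation of −0.22 between the diets. On medium fat, 64 genes lay at least 2-fold apart at a minimum of 500 UMIs and 46 at 1000 UMIs. Without doublet removal 48 did, and 62 with the doublet score's own threshold. On low fat 98 did at 1000 UMIs. Stellate-like nuclei numbered 195 in Run medium fat, 104 in Run low fat, 816 in Sed medium fat and 272 in Sed low fat. Fewer nuclei were summed on low fat, so counting error was larger there. The larger number of genes on low fat therefore does not show that stellate-like nuclei differed more in that diet.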

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

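The tests of clock phase, exchanged labels, the share against Sed low fat, hepatocyte recovery, the mixed cluster, shared lung barcodes and the source of the lung reads were chosen after the results were seen, as was judging the share at 500 and 2000 UMIs beside 1000, and a first clock test on 4 genes was dropped because they had been picked from their values. Thinning under a common minimum was added after the data had been examined, though before its outcome was known, and a test of scaling by TMM factors was dropped because a factor per library cannot move a correlation.

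The ratios of Sed over Run in hepatocyte-like nuclei ran opposite ways in the 2 diets, with a correlation of −0.53 across genes. The correlation stayed at −0.45 with nuclei thinned to 1000 UMIs under a common minimum of 2000 UMIs. This argues against unequal minimums, or the larger weight of deep nuclei, as the whole cause. Thinning came after clustering and naming and leaves the expected profile of each nucleus unchanged. It therefore cannot decide whether depth acted through the classes or through free RNA. A difference in clock phase between the pools, from the hour of collection or of feeding, stays open. Directions were taken from 17 of 20 clock genes in hepatocyte-like nuclei, where the mean log2 of Run low fat and Sed medium fat against the other pair was 1.05. That mean was 0.36 (0.13 to 0.61 when genes were redrawn) in endothelial-like nuclei, with 13 of 17 genes in the same direction. In stellate-like nuclei it was 0.27 (−0.08 to 0.65), with 8 of 15. With hepatocyte RNA subtracted the means were −0.21 (−0.95 to 0.38), with 7 of 14, and 0.29 (−0.15 to 0.72), with 7 of 13. Subtracted counts below 0 were set to 0, which can let 1 gene weigh heavily. Arntl stood at 11.5 CPM in endothelial-like against 71.7 in hepatocyte-like nuclei of Sed low fat before subtraction. The subtracted list therefore cannot settle the question. Nr1d1, picked from its values, stood at 18.2, 45.1, 49.98 and 18.7 CPM in endothelial-like against 5.46, 46.4, 44.6 and 9.08 in hepatocyte-like nuclei in the order Run medium fat, Run low fat, Sed medium fat and Sed low fat, too high for hepatocyte RNA alone. An exchange of 2 labels stays open because all pools are male (Y-linked genes differed by at most 1.122 times), and a real dependence of the mother's effect on diet stays open as untested.

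The share of endothelial-like nuclei in Sed medium fat was 3.368 times that in Run medium fat and 2.122 times that in Sed low fat. At common minimums of 500, 1000 and 2000 UMIs the first ratio was 0.956 (0.930 to 0.983), 1.244 (1.208 to 1.281) and 1.829 (1.731 to 1.932) and the second 0.899 (0.876 to 0.923), 1.623 (1.567 to 1.682) and 4.453 (4.022 to 4.93), so the gap depends on the minimum, and unequal minimums or depth cannot be told apart from a difference between the groups' livers, which stays open as untested. Poorer recovery of hepatocyte nuclei stays open. Per hepatocyte-like nucleus the classes moved apart between Sed and Run medium fat, by 7.763 times (6.374 to 9.455) for Kupffer-like, 5.872 (5.338 to 6.458) for endothelial-like, 3.795 (3.221 to 4.472) for stellate-like and 1.508 (1.236 to 1.84) for T, NK and B cell-like nuclei, and with mixed clusters counted in by 1.832 (1.647 to 2.038), 3.252 (3.002 to 3.523) and 2.792 (2.431 to 3.206) for the first 3. These ratios cannot decide it, because they were taken only at unequal minimums, 2495.5 UMIs in Run and 1597.3 in Sed medium fat. Median depth relative to the library was 0.8 in the largest endothelial-like cluster, 0.82 in Kupffer-like and 0.86 in stellate-like nuclei. It was 1.02 in T or NK and 1.07 in B cell-like nuclei, so unequal minimums could also spread the classes. All these ratios lie above 1, their order depends on where mixed nuclei are put, and T or NK cell-like nuclei carried hepatocyte markers themselves (1.61% of UMIs in Run medium fat). Hepatocyte RNA moving endothelial nuclei into the mixed cluster leaves a gap at the minimums used, of 1.865 (1.768 to 1.967) times with that cluster counted in.

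Sftpc, a surfactant gene of the lung, took 2.05% of UMIs in barcodes with 10 to 100 UMIs of Run medium fat, 1.84% in Run low fat, 3.31% in Sed medium fat and 0.962% in Sed low fat, barcodes outside the nuclei compared that served to leave out genes and as a free RNA profile. Barcodes with at least 5 Sftpc UMIs numbered 898, 724, 1398 and 467, of which 407 were common to all 4 libraries where independent draws give 2.16e-07, as reads of another library assigned by a shared sample index could produce. Separate lung tissue in each pool without misassigned reads is argued against, since even the pair with the least overlap shared 413 where chance gives at most 1.0. Lung tissue in the Sed medium fat pool as the source of the reads elsewhere is argued against too: at barcodes of its Sftpc-led cluster (123 nuclei, all of that library) the others held 47.5%, 34.95% and 21.9% as many UMIs, against 0.489%, 0.405% and 0.452% at its 10605 other nuclei, a ratio of at least 48.4 between these percentages. Some lung material in that pool besides stays open, as 3, 1, 75 and 0 nuclei held such barcodes, and no biological explanation was tested.

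Other results stood out because the 2 arms of a contrast lay in opposite directions, and these differences were not tested. Sed over Run on medium and on low fat lay at −0.30 and 0.43 for periportal genes (median difference −0.94), −0.44 and 0.43 for acute phase genes (−0.89) and 0.40 and −0.41 for interferon genes (1.02). One-carbon genes lay at −0.20 and 0.64 (−0.99), amino acid genes at −0.22 and 0.38 (−0.39), mitochondrially encoded transcripts at −0.33 and 0.33 (−0.65) and ribosomal protein genes at −0.01 and 0.44 (−0.50). Immediate early genes differed by −0.53, with medium over low fat at −0.41 in Sed and 0.23 in Run. Among single genes, the differences were −4.96 for Bhmt, 4.70 for Hsd17b6, −4.29 for Moxd1, −4.26 for Insig2, 4.25 for Arrdc3, −4.09 for Scara5, −4.00 for Pdgfrl and −4.00 for Cyp4a10.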

How the results depend on the processing

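No paired analysis was possible because no replicate numbers in the labels link libraries of different groups. Sed and Run could be set against each other over both diets with an additive model of mother and diet, but its 1 residual degree of freedom would be the mother by diet part, which took 55.3% of the sum of squares, and it was not fitted. Chosen after the data were seen were counting mixed clusters in the class that shares their leading genes, the doublet score's own threshold, free RNA from barcodes with 100 to 500 UMIs, thinning under a minimum of 2000 UMIs, TMM factors with genes of 2 to 50 CPM and, for expression, resolutions 0.5 and 2.0 and the 10% mitochondrial limit. Over the 19 alternatives that keep the hepatocyte-like class, the Pearson correlation lay between −0.58 and −0.33 for Sed over Run between the diets and between −0.41 and −0.14 for the diets between Sed and Run. TMM and DESeq2 factors add 1 constant to all genes of a contrast and so cannot move a correlation over given genes, nor set a list apart from random lists. Of 67 list medians that stood apart, 67 kept their sign with TMM factors or with DESeq2 size factors, 65 with genes from 2 CPM, 66 at resolution 2.0 and 55 with all nuclei summed without classes. Of the 67, 19 no longer stood apart with all nuclei summed, 14 with thinning under a minimum of 2000 UMIs, 8 at resolution 2.0, 7 with genes from 2 CPM, 6, 5 and 3 at minimums of 1000, 500 and 2000 UMIs, 5 with nuclei thinned to 1000 UMIs and 4 with the mean of CPM per nucleus. Of those that could be measured, 13 of 48 no longer did with TMM factors and genes of 2 to 50 CPM (5 turned sign), 12 of 52 and 4 of 56 with free RNA of barcodes with 10 to 100 and with 100 to 500 UMIs subtracted, and 4 of 52 with genes from 50 CPM. Under 5 other settings 1 or 2 were lost. Of 345 log2 ratios of named genes, 345 kept their sign with TMM factors, 343 with nuclei thinned to 1000 UMIs and 341 with thinning under a minimum of 2000 UMIs. At resolution 2.0, 340 of 344 kept it, and with all nuclei summed 322 of 339. Without a change of sign, 111 of 345 left their counting interval with TMM factors and 119 with DESeq2 size factors. All 28 class shares stayed within their interval at resolution 0.5 and with the 10% limit. Free RNA subtraction with barcodes of 10 to 100 UMIs took between 21.55% (Sed low fat) and 35% (Sed medium fat) of hepatocyte-like UMIs, a share set by markers of other cell types, Stab2 among them. Those barcodes held between 0.19% and 0.39% of a library's UMIs and carried lung transcripts, so this setting need not match the free RNA of most empty droplets. It left 284 ratios to compare. Stellate-like nuclei at a minimum of 2000 UMIs were under 100 in a library and gave no value. All nuclei summed hold the other cell types by construction, and a gene minimum sets how many genes are counted. The cause of the other shifts was not tested. Of 28 shares over 7 classes, 24, 26 and 16 left their interval at minimums of 500, 1000 and 2000 UMIs, 15 at resolution 2.0, 14 without doublet removal, 9 with the doublet score's own threshold and 3 with mitochondrial UMIs under 1%, and so did 15 of 16 with mixed clusters counted in. Given below by setting are hepatocyte-like and endothelial-like shares outside their binomial interval, correlations outside the range of redrawn genes, numbers of genes or lists that moved by over 1.5 times, and medians or ratios that turned sign. Values for the diets are medium over low fat.

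With DESeq2 size factors, genes at least 2-fold apart were 103 higher for Sed over Run on medium fat and 169 higher and 167 lower for the diets in Sed. With TMM factors, the 2-fold counts were 109 higher for Sed over Run on medium fat. With TMM factors with genes of 2 to 50 CPM, the Pearson correlation was −0.41 for Sed over Run between the diets and −0.21 for the diets between Sed and Run. Genes 2-fold or more apart numbered 294 higher and 144 lower for Sed over Run on medium fat, 353 higher for the diets in Run and 455 higher for the diets in Sed. Lists apart from random lists were 9 for Sed over Run on low fat. List medians that turned sign were −0.17 for immediate early and −0.59 for oxidative stress (Sed over Run on low fat), 0.62 for immediate early (the difference of differences), −0.07 for immediate early (the diets in Run) and −0.07 for lipid droplet (Sed over Run on medium fat). With all nuclei summed without classes, the Pearson correlation was 0.25 for Sed over Run between the diets and 0.16 for the diets between Sed and Run. Genes at least 2-fold apart were 632 higher for Sed over Run on low fat, 802 higher and 195 lower for Sed over Run on medium fat, 443 higher for the difference of differences, 438 higher for the diets in Run and 420 higher and 193 lower for the diets in Sed. Lists apart from random lists were 10 for Sed over Run on low fat, 22 for Sed over Run on medium fat and 19 for the diets in Sed. Of the lists, sign turned at −0.05 for bile acid synthesis, 0.18 for interferon response, −0.10 for pericentral hepatocyte genes and −0.04 for secreted hepatocyte transcripts (Sed over Run on low fat), −0.29 for circadian clock, −0.07 for fatty acid synthesis, −0.13 for fatty acid oxidation and 1.46 for ribosomal proteins (Sed over Run on medium fat), −0.04 for male-biased liver genes (the diets in Run), −0.04 for pericentral hepatocyte genes and 1.34 for ribosomal proteins (the diets in Sed) and 1.10 for ribosomal proteins (the difference of differences). Reversed log2 ratios were BC028777 −0.08, Rpl19 1.56, Rpl4 0.90, Rpl5 0.72 and Rps18 0.61 for Sed over Run on medium fat, Herc6 0.36 and Parp14 0.34 for Sed over Run on low fat, Hsp90aa1 0.06, Rpl13 1.33, Rpl19 1.38, Rpl23 1.44 and Rpl4 0.50 for the diets in Sed and Rpl13 0.80, Rpl19 1.00, Rpl41 0.59 and Rps2 0.26 for the difference of differences. With the free RNA of barcodes with 10 to 100 UMIs subtracted, the Pearson correlation was −0.33 for Sed over Run between the diets and −0.14 for the diets between Sed and Run. The 2-fold counts were 448 higher and 296 lower for Sed over Run on low fat, 440 higher and 401 lower for Sed over Run on medium fat, 411 higher and 477 lower for the diets in Run, 417 higher and 526 lower for the diets in Sed and 828 lower for the difference of differences. Lists apart from random lists were 6 for Sed over Run on medium fat. Turned list medians were −0.09 for lipoproteins (Sed over Run on low fat). Reversed log2 ratios were Stab2 −8.63 for Sed over Run on low fat. With the free RNA of barcodes with 100 to 500 UMIs subtracted, the Pearson correlation was −0.50 for Sed over Run between the diets. List medians that turned sign were −0.04 for male-biased liver genes (the diets in Run). With genes from 2 CPM, the Pearson correlation was −0.43 for Sed over Run between the diets and −0.25 for the diets between Sed and Run. Genes 2-fold or more apart numbered 400 higher and 344 lower for Sed over Run on low fat, 526 higher and 147 lower for Sed over Run on medium fat, 1392 higher and 611 lower for the difference of differences, 438 higher and 335 lower for the diets in Run and 693 higher and 171 lower for the diets in Sed. Of the lists, sign turned at −0.11 for immediate early (the diets in Run) and 0.02 for ribosomal proteins (Sed over Run on medium fat). With genes from 50 CPM, the Pearson correlation was −0.58 for Sed over Run between the diets and −0.41 for the diets between Sed and Run. Genes at least 2-fold apart were 109 higher and 84 lower for Sed over Run on low fat, 65 higher and 53 lower for Sed over Run on medium fat, 294 higher and 213 lower for the difference of differences, 110 higher and 82 lower for the diets in Run and 90 higher and 64 lower for the diets in Sed. Turned list medians were −0.16 for male-biased liver genes (the diets in Run). With the mean of CPM per nucleus, the Pearson correlation was −0.49 for Sed over Run between the diets. List medians that turned sign were 0.04 for ribosomal proteins (Sed over Run on medium fat). With a minimum of 1000 UMIs, the hepatocyte-like share was 58.43% in Run low fat, 35.41% in Run medium fat, 43.03% in Sed low fat and 23.93% in Sed medium fat. The endothelial-like share was 22.62% in Run low fat, 36.05% in Run medium fat, 27.63% in Sed low fat and 44.85% in Sed medium fat. In stellate-like nuclei the genes at least 2-fold apart numbered 98 for Sed over Run on low fat, 46 for Sed over Run on medium fat, 96 for the diets in Run and 91 for the diets in Sed. With a minimum of 2000 UMIs, the hepatocyte-like share was 46.92% in Run medium fat, 54.06% in Sed low fat and 34.79% in Sed medium fat. The endothelial-like share was 5.865% in Run low fat, 19.56% in Run medium fat, 8.033% in Sed low fat and 35.77% in Sed medium fat. In endothelial-like nuclei the genes at least 2-fold apart numbered 57 for the diets in Sed. With a minimum of 500 UMIs, the hepatocyte-like share was 52.06% in Run low fat, 26.56% in Run medium fat, 34.57% in Sed low fat and 16.27% in Sed medium fat. The endothelial-like share was 27.57% in Run low fat, 34.87% in Run medium fat, 37.09% in Sed low fat and 33.34% in Sed medium fat. In endothelial-like nuclei the genes at least 2-fold apart numbered 98 for the diets in Run and 61 for the diets in Sed. In stellate-like nuclei the genes at least 2-fold apart numbered 64 for Sed over Run on medium fat, 250 for the diets in Run and 204 for the diets in Sed. With mitochondrial UMIs under 1%, the hepatocyte-like share was 53.54% in Run medium fat. With mixed clusters counted in, the hepatocyte-like share was 70.23% in Run low fat, 53.75% in Run medium fat and 50% in Sed low fat. The endothelial-like share was 17.19% in Run low fat, 22.65% in Run medium fat, 28.6% in Sed low fat and 42.24% in Sed medium fat. With no doublet removal, the hepatocyte-like share was 66.3% in Run low fat, 50.14% in Run medium fat, 45% in Sed low fat and 28.22% in Sed medium fat. The endothelial-like share was 7.252% in Run low fat, 11.13% in Run medium fat, 17.93% in Sed low fat and 38.54% in Sed medium fat. In endothelial-like nuclei the genes at least 2-fold apart numbered 22 for Sed over Run on medium fat. In stellate-like nuclei the genes at least 2-fold apart numbered 48 for Sed over Run on medium fat. With the doublet score's own threshold, the hepatocyte-like share was 66.35% in Run low fat, 50.09% in Run medium fat and 44.97% in Sed low fat. The endothelial-like share was 11.12% in Run medium fat and 17.88% in Sed low fat. In endothelial-like nuclei the genes at least 2-fold apart numbered 23 for Sed over Run on medium fat. In stellate-like nuclei the genes at least 2-fold apart numbered 62 for Sed over Run on medium fat. With resolution 2.0, the hepatocyte-like share was 63.61% in Run low fat, 47.57% in Run medium fat, 45.44% in Sed low fat and 26.05% in Sed medium fat. Of the lists, sign turned at −1.07 for pericentral hepatocyte genes (the diets in Sed). Reversed log2 ratios were Cyp2a5 −0.05, Lgr5 −1.17, Slc1a2 −1.66 and Tbx3os1 −1.40 for the diets in Sed. With nuclei thinned to 1000 UMIs, the Pearson correlation was −0.43 for Sed over Run between the diets. Turned list medians were 0.07 for ribosomal proteins (Sed over Run on medium fat). Reversed log2 ratios were mt-Co2 0.05 for Sed over Run on medium fat and mt-Co2 0.00 for the difference of differences. With nuclei thinned to 1000 UMIs under a minimum of 2000 UMIs, the Pearson correlation was −0.45 for Sed over Run between the diets and −0.28 for the diets between Sed and Run. List medians that turned sign were 0.03 for ribosomal proteins (Sed over Run on medium fat). Reversed log2 ratios were Rpl19 0.05 and mt-Cytb 0.02 for Sed over Run on medium fat, Rpl19 0.01 for the difference of differences and mt-Atp6 −0.12 for Sed over Run on low fat.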

Other observations

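The values below were chosen after the data were seen, without a test of any explanation. In endothelial-like nuclei the interferon list, with Parp14 among its 9 measured members, had a median log2 ratio of 0.46 for medium over low fat in Sed, with all 9 higher, and of −0.11 for Sed over Run on low fat. In stellate-like nuclei these medians were 0.76 and −0.29 over 11 members, and the difference of differences was 0.96. The clock list members above the 50 CPM minimum had a median of −0.20 over 7 in endothelial-like and −0.50 over 9 in stellate-like nuclei for Sed over Run on medium fat. Members below that minimum went both ways in endothelial-like nuclei. Nr1d1 stood at 18.2 CPM in Run and 49.98 in Sed, Dbp at 28.9 and 67.1, and Cry1 at 47.95 and 20.3. Each of these went the same way as in hepatocyte-like nuclei, where they stood at 5.46 and 44.6, 10.9 and 68.2, and 62.4 and 18.5 CPM. Others did not, such as Per1, at 45.7 and 39.7 CPM against 58.0 and 69.1 in hepatocyte-like nuclei. These medians therefore do not describe the clock list as a whole. Periportal hepatocyte genes lay at −0.69 in endothelial-like nuclei in that contrast, where hepatocyte markers took 0.46% of the UMIs of these nuclei in Run and 0.32% in Sed.

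Other genes differed between the libraries in stellate-like nuclei. Zbtb16 stood at 1508, 475.7, 968.8 and 2133 CPM in Run medium fat, Run low fat, Sed medium fat and Sed low fat, below its level in hepatocyte-like nuclei (1951, 814, 1164 and 2271 CPM). Adam23 stood at 283, 63.2, 173 and 206 CPM and was 2.13 higher on the log2 scale on medium than on low fat in Run (1.45 to 2.97).

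With the mixed clusters led by the same genes counted in, stellate-like nuclei came to 5.48% of nuclei in Run medium fat, 3.52% in Run low fat, 8.78% in Sed medium fat and 5.53% in Sed low fat.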
